A study of Mus musculus with 2 samples.

How the data were processed

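The data are 2 droplet libraries of islet cells, 1 from NOD mice fed HAMS and 1 from NOD mice fed HAMSAB, grouped by the treatment label. The labels do not say how many mice went into a library. Per the labels' protocols the islets were isolated by a published procedure and captured with a Chromium 3' kit. Per the file headers the count matrices were written by Cell Ranger 5.0.0, and each deposited value is a raw count of UMIs for 1 gene in 1 barcode, with no normalization. The genome builds mm10 and GRCm38 and the tool Seurat are named in the submitters' processing notes. The cell calling settings, the annotation release and any filter applied before deposit are not given in the sources used here. The authors also deposited 8 tables of their own comparisons between the diets, with a log2 fold change and an adjusted p-value per gene, both as the authors computed them from cells. The test and the normalization behind these deposited values are not given in the sources used here. No such table gives the values of a sample, so they have no n, and no p-value of theirs is a test across mice.

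The matrices list 32285 genes. Cells were kept with at least 200 genes and at most 20% mitochondrial UMIs. The filter on genes removed 161 of 4352 HAMS barcodes (3.70%) and 389 of 5022 HAMSAB barcodes (7.75%), and the filter on mitochondrial UMIs removed 6 and 5. Kept cells held a median of 704 UMIs in HAMS and 705 in HAMSAB, so most genes have under 1 UMI per cell, and values rest on sums over cells. Actb alone took 15.4% of HAMS and 17.7% of HAMSAB UMIs. Doublets were called in each library with Scrublet as implemented in scanpy 1.11.5, with an expected rate of 5%. It marked 4 of all cells (0.0454%). A caller that marks under 0.5% was taken not to have worked, so all cells were kept and doublets remain in every class. Keeping doublets, listed as an alternative beforehand, is therefore the same as the reported setting.

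Both libraries were clustered together without integration. Genes seen in at least 3 cells entered, each cell was scaled to 10000 UMIs and log-transformed, and 2000 variable genes, 30 principal components, 15 neighbours and Leiden clustering at resolution 1 (igraph 0.11.9) gave the clusters. A cluster was given the class whose fixed markers had the highest mean standardized level in it, called X-like, if at least 3 of these markers were detected in at least 5% of its cells and its 10 leading genes did not hold more markers of another class than of its own. Alpha-like cells are cluster 0, delta-like 2, beta-like 3, 4 and 5, pDC-like 7, cDC-like 1 and 8, macrophage-like 9, B-like 10, T-like 11, ductal-like 12, endothelial-like 13, plasma-like 14 and acinar-like 15. Cluster 6 scored highest for cDC markers, but its 10 leading genes (Ifitm1, Il1r2, Pak1, Adam23, S100a4, Tbc1d4, Havcr2, Mndal, Plbd1 and Kit) held none of them and 1 mast cell marker, so it stayed unnamed. That handling was settled after its genes were seen. Gamma cells, which carry Ppy, were not set apart from alpha-like cells at this resolution.

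Within each class of at least 20 cells per library, raw UMIs were summed per library and divided by the class total to give CPM. The log2 ratio of HAMSAB over HAMS has an exact conditional binomial 95% interval, each CPM an exact Poisson interval and each share of cells an exact Clopper-Pearson interval. All of these cover counting error only. No test was made, because cells of 1 library are not replicates of a diet. Genes with at least 50 UMIs over both libraries were counted as apart when at least 2-fold higher or lower, and 20 simulated pairs of libraries that differ by counting error alone gave the number to set beside that count. Genes were named by a rule of size: among genes with at least 50 UMIs, the 12 highest and 12 lowest in beta-like cells and the 6 highest and 6 lowest elsewhere, ranked by the interval bound nearest 0. Mitochondrial and ribosomal protein genes, genes with Gm or Rik names, immunoglobulin and T cell receptor segments, haemoglobins and genes under 0.1 of their highest CPM among the classes in both libraries (possible free RNA) were left out of that ranking. Besides these the rule takes the islet hormones in endocrine classes, up to 2 highest and 2 lowest members of each list and up to 3 genes in each direction from each of the authors' deposited tables. For beta-like cells, 1 gene that the rule takes is not reported here. The cell type markers, the gene lists, this rule and the filters were fixed before the data were examined. Which of the named list members and of the genes in small classes the text gives was chosen after their values, those under the alternatives included, were seen, and some genes left out changed sign under an alternative.

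For each of 26 fixed gene lists, members with at least 20 UMIs over both libraries were taken, and the percentile of their median log2 ratio among 10000 random lists of the same size, matched in 20 bins of mean CPM, describes these libraries and is no test. The lists are beta cell identity, insulin granule processing and secretion, disallowed and dedifferentiation genes, alpha cell identity, delta cell identity, the unfolded protein response, the interferon response, MHC class I and class II presentation, oxidative phosphorylation, glycolysis, the antioxidant response, immediate early and dissociation stress, ribosomal proteins, apoptosis, the cell cycle, the Reg family, short-chain fatty acid receptors and histone deacetylases, T cell effector genes, T cell inhibitory receptors and regulatory markers, T cell naive and memory genes, B cell activation, macrophage inflammatory and homeostatic genes, pDC function and sex-linked genes. Of all pairs of a list and a class, the text gives every median outside the central 95% of random lists, a rule set after the medians were seen, and each list in the class it was written for or in beta-like cells. Ddit3, Aldoa and Mx1 were not used, since their symbols match no row or more than 1 row of the matrices. Coordinates come from GENCODE M21 on GRCm38, matched by gene identifier.

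The ratio and its interval were tested on simulated data for HAMSAB against HAMS over all cells, with 9738 genes, of which 200 were drawn for a known change and those that stayed above the count limit were read. For 50 genes set to a log2 ratio of 2 the median recovered was 2.00 with 96.0% of intervals covering it, and 50 were at least 2-fold apart. For 50 genes set to 1 the values were 1.06 and 98.0%, with 30 genes at least 2-fold apart. For 44 genes set to -1 they were -0.98 and 95.5% with 18 genes, and for 41 genes set to -2 they were -2.04 and 95.1% with 39 genes. Among 9553 genes with no change 17 were at least 2-fold apart. On the same genes a simulated list of 25 unmoved genes came out at percentile 50.6, and at 100 once its members were raised by 0.5. All simulated counts were drawn with counting error alone, the model behind the interval, so coverage near 95% checks the calculation only. The simulation does not cover UMIs that gather in few cells, as those of Sst in beta-like cells do.

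The alternatives were at least 500 genes per cell, at most 10% mitochondrial UMIs, Leiden resolutions 0.5 and 2, classing each cell by its own markers, CPM without hormone genes, centring on the median gene, equal weight per cell, cells thinned to 1000 UMIs, and other UMI minimums for genes and list members. Added after the data were seen were CPM without Actb, each beta cluster alone, removal of the 4 cells Scrublet marked and removal of the 5% of cells with the highest Scrublet scores. Other tools were anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, scikit-image 0.26.0 and matplotlib 3.10.9 under Python 3.11.15.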

Results

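Single-cell RNA sequencing was done on pancreatic islets of NOD mice, an inbred strain that develops autoimmune diabetes through infiltration of the islets by immune cells. The mice were 5 weeks old when they started on 1 of 2 diets and ate it for 5 weeks. One diet is labelled HAMS, known in the field as a high-amylose maize starch, and the other HAMSAB, the same starch carrying acetyl and butyryl groups, which gut bacteria release as the short-chain fatty acids acetate and butyrate. Each diet has 1 library made with droplet 3' chemistry. The HAMS library held 4352 barcodes and 3599756 unique molecular identifiers (UMIs), and the HAMSAB library 5022 barcodes and 4254040 UMIs. After the cell filter 4185 HAMS cells with a median of 704 UMIs and 383 genes remained, against 4628 HAMSAB cells with a median of 705 UMIs and 378 genes. With 1 library per diet no difference has a replicate check, no test between the diets exists, and every interval given is a 95% interval that covers counting error only. Xist was detected with 1571 UMIs in the HAMS and 1916 in the HAMSAB library, while Ddx3y, Uty, Eif2s3y and Kdm5d gave at most 2 UMIs each in either.

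The comparison of cell classes asks which cells the islets of each diet held. Endocrine cells were a smaller part of the HAMSAB library and lymphocytes a larger one. Beta-like, alpha-like and delta-like cells together made up 56.3% of HAMS cells (interval 54.8 to 57.8) and 29.8% of HAMSAB cells (28.5 to 31.1). Named immune classes made up 25.2% (23.9 to 26.6) and 48.0% (46.6 to 49.5). B-like cells had the largest ratio among the classes with at least 20 cells per library, 3.04-fold (2.60 to 3.55), with 4.59% of HAMS and 13.9% of HAMSAB cells. T-like cells were 7.53% of HAMS and 15.1% of HAMSAB cells, plasma-like cells 0.502% and 1.32%, and plasmacytoid dendritic (pDC-like) cells 0.789% and 1.45%. Macrophage-like cells differed less, 6.71% against 8.36%, as did conventional dendritic (cDC-like) cells, 5.09% against 7.89%. Cluster 6, an immune cluster left without a name, held 15.3% of HAMS and 17.4% of HAMSAB cells. Islets were isolated from the pancreas before capture, and that step sets how much tissue around the islets is carried along. Ductal-like cells were 75 of 4185 HAMS cells (1.79%, 1.41 to 2.24) and 185 of 4628 HAMSAB cells (interval 3.45 to 4.60%), and acinar-like cells were 0 of 4185 (upper bound 0.0881%) and 9 of 4628. Endothelial-like cells, whose cluster was also led by the fibroblast genes Col1a1 and Dcn, were 1.39% and 0.605%. Within the endocrine cells the composition was closer: beta-like cells made up 58.0% (55.9 to 60.0) in HAMS and 53.4% (50.8 to 56.1) in HAMSAB, alpha-like cells 22.8% and 22.1%, and delta-like cells 19.3% (17.7 to 20.9) and 24.4% (22.2 to 26.8). With each cell classed by its own markers, without clusters, the endothelial difference turned to 0.943 percentage points in favour of HAMSAB and the ductal difference shrank from 2.21 to 0.575. With at least 500 genes required per cell the endocrine difference was -17.1 in place of -26.5 percentage points and the beta difference -7.07 in place of -16.7, while the macrophage difference was -0.0957. That setting left 185 cells without a class name, of them 2 from cluster 6, with a share difference of -7.50 points. The smaller endocrine and beta differences may thus in part reflect cells without a class name. The cDC difference of 2.80 points was between 3.61 and 5.01 in the other clusterings and 1.60 by single-cell classing, but there 38.9% to 76.5% of the cDC-like cells came from cluster 6.

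**Figure D1:**
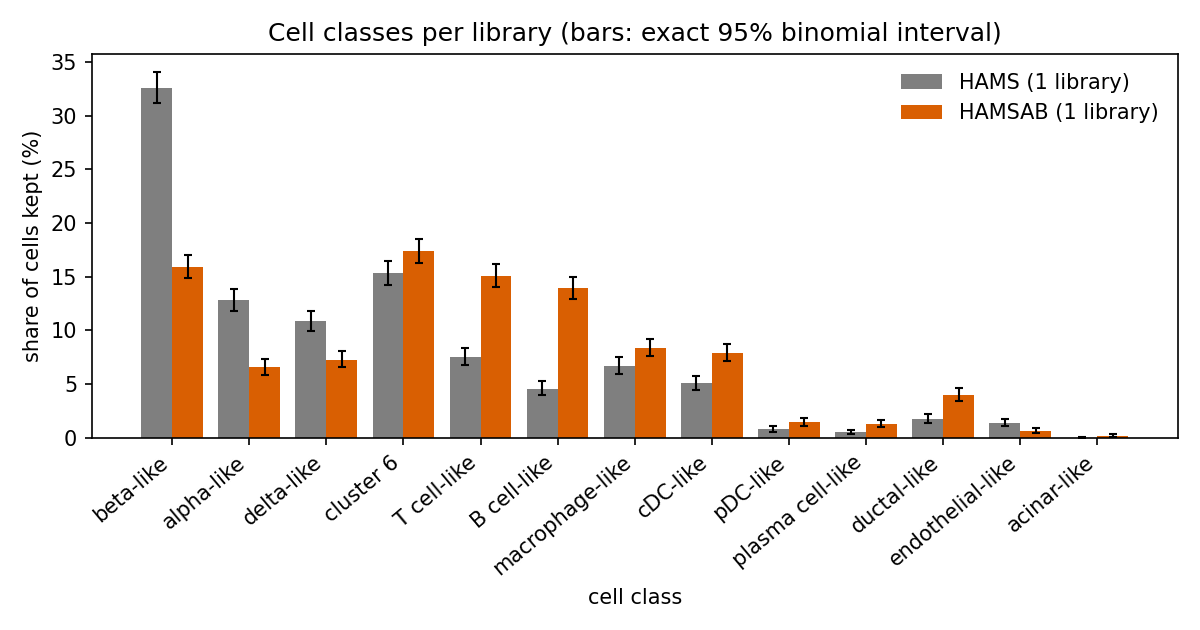
Share of the cells kept in each library (percent, vertical axis) for each cell class (horizontal axis), HAMS in grey and HAMSAB in orange, 1 library each, with exact 95% binomial intervals. The 3 endocrine classes were lower in HAMSAB (beta-like 32.6% against 15.9%) and B-like and T-like cells higher.

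In beta-like cells of the HAMSAB library Iapp and Scg2 RNA was higher, Dnajb1 RNA was lower, and the list of immediate early and dissociation stress genes was lower as a group. Iapp, which encodes the amyloid peptide that beta cells release with insulin, stood at 7906 CPM (UMIs scaled to the class total) in HAMS and 14687 CPM in HAMSAB, a log2 ratio of 0.89 (0.85 to 0.93). Scg2, a granin of the secretory granule, was higher by a log2 ratio of 0.93 (0.85 to 1.01), and Ins1 and Ins2 by 0.22 (0.20 to 0.25) and 0.16 (0.14 to 0.17). The chaperone gene Dnajb1 was lower with -1.11 (-1.33 to -0.90). The comparison covered 1365 HAMS and 737 HAMSAB cells and 4681 genes with at least 50 UMIs, of which 63 were at least 2-fold higher and 84 at least 2-fold lower in the HAMSAB library. Counting error alone gave on average 20.4 such genes in simulated pairs of libraries.

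Among the other genes picked by the size of their counting bound, the highest ratios in beta-like cells were those of Dapl1 (2.82, interval 2.34 to 3.34) and Gc (2.23, 1.81 to 2.67). Gc, which encodes the vitamin D binding protein, and Ttr, transthyretin (1.06), are on the fixed list of alpha cell markers. They were followed by Pigr (1.83), Ocrl (1.74), Spc25 (1.60), Nucb2 (1.54), the prodynorphin gene Pdyn (1.48), Chac1 (1.44), a target of the integrated stress response, and Ttyh1 (1.31). The genes picked on the lower side were Sult1c2 (-2.04), the clock gene Per3 (-1.91), Fhad1 (-1.87), Stxbp5l (-1.83), the activity-induced transcription factor Npas4 (-1.82), Mast3 (-1.55), Fnip2 (-1.23), Pcsk1n (-1.09), Impact (-1.04) and Dbpht2 (870 CPM in HAMS and 435 in HAMSAB). Stxbp5l is also among the leading genes of the delta-like cluster. Hormone RNA of other islet cells was lower in HAMSAB beta-like cells, with ratios of -0.69 for Gcg, -1.92 for Sst and -2.42 for Ppy over all their clusters. Beta-like cells fell into 3 clusters. Cluster 3 held the most in HAMS (48.4%, against 34.5% in HAMSAB) and cluster 4 the most in HAMSAB (47.5%, against 44.8%). Cluster 5 was led by interferon-induced genes together with Dapl1, Chac1 and Iapp, so its size was not compared. Within clusters 3, 4 and 5 alone the ratio of Dapl1 was 2.69, 2.60 and 2.68, that of Iapp 0.54, 0.82 and 0.66, and that of Chac1 1.26, 1.11 and 2.37. Sst turned to 4.36 in cluster 5 alone and Gcg to 0.02 in cluster 4 alone. Ins1 and Ins2 went opposite ways by cluster, with -0.45 and -0.52 in cluster 3, 0.80 and 0.73 in cluster 4, and 0.60 and 0.63 in cluster 5.

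**Figure D2:**
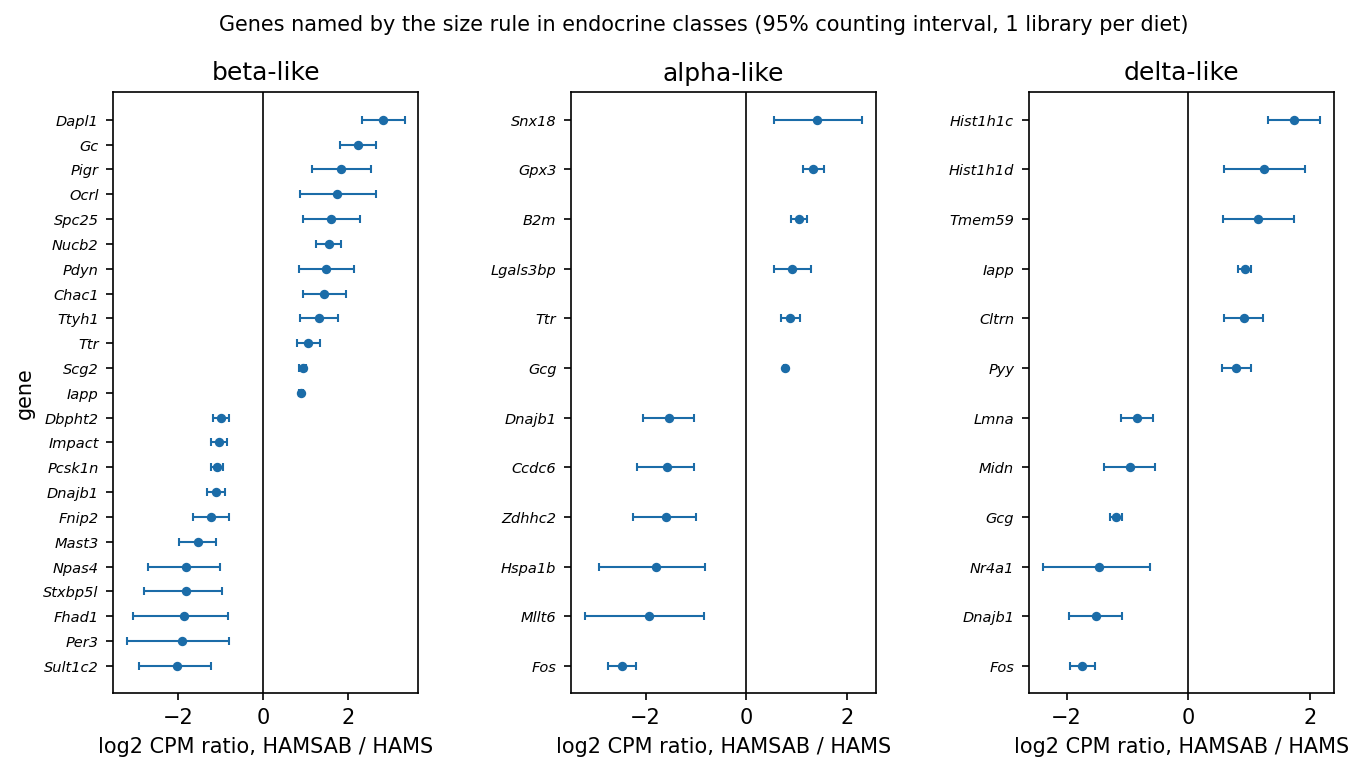
Log2 CPM ratio of HAMSAB over HAMS (horizontal axis) for genes picked by the size rule (vertical axis) in beta-like, alpha-like and delta-like cells, with 95% counting intervals from 1 library per diet. Of the genes plotted, which leave out hormones taken for another reason, Dapl1 had the highest value in beta-like cells (2.82), and Fos the lowest in alpha-like (-2.47) and delta-like cells (-1.74).

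Gene lists were read as the median log2 ratio of their members and its percentile among 10000 random lists of matched expression, over 131 pairs of a list and a class, of which 8 lay under the 2.5th and 11 over the 97.5th percentile. In beta-like cells the list of immediate early and dissociation stress genes was lower, with a median of -0.34 (-0.44 to -0.23) below all but 0.01% of random lists. Of its 24 measured members 18 were lower in HAMSAB, among them Dusp1 (-0.82) and Hspa1a (-1.02), while Klf6 was higher (0.81). The median was nearer 0 within cluster 3 (-0.14) and cluster 5 (-0.06), and -0.41 within cluster 4. Interferon response genes had a median of -0.27 (-0.35 to -0.10; percentile 0.23), with 23 of 30 lower, among them Gbp3 (-0.91) and Irf7 (-2.59 from 18 and 2 UMIs). Within clusters 3, 4 and 5 alone that median was lower still, -0.41, -0.79 and -0.54. The interferon-led cluster 5 held a larger part of the HAMSAB beta-like cells (18.0%, against 6.89% in HAMS), so the pooled median also reflects the mix of clusters. Interferon-induced genes helped to set that cluster apart, so the medians within clusters depend on that split. Glycolysis genes had a median of -0.46 (percentile 1.25), with 8 of 10 lower, and -0.09 within cluster 5. The list of genes normally kept off in beta cells or used as signs of lost identity had -0.69 (percentile 0.470) over 7 measured members, 3 of them the hormones Gcg, Sst and Ppy, and another Ldha (-2.16 from 20 and 3 UMIs). This median is the ratio of Gcg itself. The median was -0.47 with each cell weighted equally, and -0.43 and -0.28 within clusters 3 and 4. It was -1.96 with at least 500 genes per cell and -1.42 at Leiden resolution 2. Beta cell identity genes had a median of 0.13 (percentile 92.5), with 15 of 25 higher, and insulin granule genes 0.13 (94.9), with 16 of 26 higher, among them Scg2, while Cplx2 was lower (-0.69). Both medians were below 0 in cluster 4 alone, -0.06 and -0.03, and the granule median was -0.02 with at least 500 genes per cell.

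The remaining lists lay within the central 95% of random lists in beta-like cells. The median was 0.11 for the unfolded protein response, 0.10 for oxidative phosphorylation (0.34 with at least 500 genes per cell, 0.28 in thinned cells, 0.29 within cluster 5 and -0.08 within cluster 3), -0.03 for the antioxidant response, 0.02 for apoptosis (-0.44 and -0.49 within clusters 3 and 5), -0.15 for the cell cycle and -0.00 for ribosomal proteins. Major histocompatibility complex (MHC) class I genes had -0.09 (-0.33 with each cell weighted equally and -0.36 within cluster 4), with B2m higher (0.58) and the immunoproteasome subunit Psmb10 lower (-2.59 from 36 and 4 UMIs). The list of short-chain fatty acid receptors and histone deacetylases had a median of -0.34 at percentile 10.1 over 7 measured members. It includes proteins through which butyrate is known to act, and also the transporter genes Slc16a1 and Slc5a8. Ffar2 had 26 and 13 UMIs, a ratio of -0.42 (-1.51 to 0.59), Hdac1 0.28 (-0.23 to 0.79) and Hdac2 -0.57 (-1.35 to 0.16), differences not detectable at this depth. Fewer than 3 genes of the Reg family reached 20 UMIs in any class, so that list has no value.

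Alpha-like cells of the HAMSAB library held more glucagon RNA and less RNA of Fos, an immediate early transcription factor. Gcg, the glucagon gene, stood at 80298 CPM in 536 HAMS cells and 136793 CPM in 305 HAMSAB cells, a log2 ratio of 0.77 (0.75 to 0.79). Gpx3, a secreted glutathione peroxidase (1.34, 1.13 to 1.54), B2m, the shared light chain of MHC class I (1.05), Ttr (0.88), Lgals3bp (0.92) and Snx18 (1.42) were also higher. Gcg and Ttr also lead the cluster by which these cells were picked. Fos was at -2.47 (-2.76 to -2.19), with 1120 and 114 UMIs. Below 0 as well were Mllt6 (-1.92), Hspa1b (-1.80), Zdhhc2 (-1.59), Ccdc6 (-1.58) and Dnajb1 (-1.53). The immediate early list had a median of -0.30 at percentile 2.27, with 18 of 23 lower and Klf6 again higher (0.81). That median was 0.01 in cells thinned to 1000 UMIs, a setting that left out 425 HAMS and 253 HAMSAB cells. Granule genes had a median of 0.15 (-0.004 to 0.30), percentile 99.2, with 14 of 24 higher, Cpe at 0.78 and Pcsk1n at -0.65. The matched random lists centred at -0.10. Alpha identity genes had a median of 0.20 (percentile 96.1), with Slc38a5 at 2.83 from 5 and 20 UMIs. The alpha identity median was 0.02 at Leiden resolution 2. Ppy had a ratio of 0.04 in this cluster, which also holds the gamma cells. Sst was lower in HAMSAB alpha-like cells (-2.19), as were Ins1 (-2.74), Ins2 (-2.83) and Iapp (-2.18). The last 3 were above 0 at Leiden resolution 2 (0.07, 0.14 and 0.27) and when each cell was classed by its own markers (0.44, 0.49 and 0.28), and Sst was at 0.12 with at least 500 genes per cell. In all, 15 genes were at least 2-fold higher and 49 lower of 1939 with at least 50 UMIs, against 10.1 from counting error alone.

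Fos was lower in delta-like cells as well, with -1.74 (-1.94 to -1.54) in 454 HAMS and 337 HAMSAB cells. Dnajb1 (-1.52), Nr4a1, another immediate early gene (-1.47), Gcg (-1.19), Midn (-0.97) and Lmna (-0.84) were lower too. Higher were the linker histone genes Hist1h1c (1.72) and Hist1h1d (1.24), Tmem59 (1.14), Iapp (0.92, 0.81 to 1.03), Cltrn (0.90) and the peptide YY gene Pyy (0.79). Sst itself, the somatostatin gene, was nearly level at -0.16 (-0.18 to -0.13), and Ppy had 0.46. Ins1 and Ins2 were at -2.93 and -2.01, but at 0.02 and 0.43 with at least 500 genes per cell, where Ppy was at -0.36. The immediate early list had a median of -0.17 (percentile 1.60), with 15 of 21 lower and Klf6 at 0.81, and delta identity genes 0.14 (percentile 76.7), which turned to -0.11 with at least 500 genes per cell and -0.16 in cells thinned to 1000 UMIs. Of 1885 genes 21 were at least 2-fold higher and 19 lower, against 8.65 from counting error alone.

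T-like cells of the HAMSAB library held more RNA of genes of naive and memory T cells and less of glycolytic genes. The naive and memory list had a median of 0.84 (0.29 to 1.04), above all random lists, with 7 of 9 members higher. Among them were Ccr7, the receptor that guides T cells to lymphoid tissue (1.33, 0.72 to 1.99), and the interleukin 7 receptor gene Il7r (1.46, from 10 and 49 UMIs), while Lef1 had -0.18. The genes picked by size on the higher side were the ligand genes Tnfsf8 (1.96, 1.33 to 2.64) and Tnfsf11 (1.60), Cd83 (1.89), the cytokine signalling inhibitor Socs1 (1.60), Ipcef1 (2.31) and Zfp36l1, an RNA-binding protein that promotes mRNA decay (1.29). Those on the lower side were D17H6S53E (-1.30), Rpn1 (-1.27), Samd1 (-1.03), Map3k1 (-0.76), Vim (-0.74) and Kdelr2 (-0.73). Effector genes had a median of -0.05 (percentile 36.6), with Nkg7 at -0.79 and Ccl5 at -0.69. At Leiden resolution 2 these were 0.49, 1.03 and 0.75, while the effector median was -0.36 in cells thinned to 1000 UMIs. Inhibitory and regulatory genes had 0.17 (percentile 84.5), with Foxp3 at 1.43 (0.01 to 3.18) from 5 and 24 UMIs and Il10 at 1.17 from 5 and 20. Glycolysis genes had -0.27 (percentile 1.63), with 10 of 11 lower, Gapdh at -0.53. Ribosomal proteins had 0.15 (percentile 98.7). Of the islet hormones, Ins2 was at 0.61 and Sst at -1.87 in these cells. The comparison covered 315 and 698 cells, and of 3151 genes 74 were at least 2-fold higher and 28 lower, against 19.1 from counting error alone.

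B-like cells of the HAMSAB library had more RNA of activation and immediate early genes. The B cell activation list had a median of 0.42 (0.04 to 0.58; percentile 99.5), with 8 of 12 higher, among them Egr1 (0.71, 0.31 to 1.12) and Fcer2a, the low-affinity IgE receptor (0.97, -0.01 to 2.11). The immediate early list had 0.39 (0.23 to 0.62), percentile 99.97, with 15 of 19 higher, Klf6 at 1.15 and Klf4 at 1.74 from 5 and 50 UMIs. Its median was 0.18 when each cell was classed by its own markers and 0.71 with at least 500 genes per cell. Beta cell hormone RNA was higher in these cells too, with Ins1 at 1.57, Ins2 at 1.32 and Iapp at 2.02, while doublets were kept. Glycolysis genes were lower here too, with a median of -0.39 (percentile 0.780) and 10 of 11 below 0, Eno1 at -0.81. MHC class II genes had 0.16 (percentile 82.8), with H2-DMb1 at 1.15 (-0.10 to 2.68). Sipa1 (2.56), Fundc2 (2.56), Uhrf2 (2.18), Crebrf (2.16), Mrps33 (2.03) and Rgs2, a regulator of G protein signalling (1.26, 0.75 to 1.81), were higher, all but Rgs2 on at most 5 UMIs in the 192 HAMS cells. Gars (-1.42), Rpap3 (-1.31), Desi2 (-1.28), the interleukin 21 receptor gene Il21r (-1.14, -1.53 to -0.75), Slc2a12 (-1.01) and Zeb2 (-0.99) were lower. Of 2548 genes 76 were at least 2-fold higher and 23 lower in the 645 HAMSAB cells, against 28.4 from counting error alone.

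Macrophage-like cells of the HAMSAB library had more RNA of genes on the macrophage inflammatory list. That list had a median of 0.45 (0.23 to 0.57), above all random lists (0.20 with each cell weighted equally, 0.92 with at least 500 genes per cell and 0.88 in cells thinned to 1000 UMIs), with 13 of 17 higher, among them Il6 (1.93, from 5 and 24 UMIs) and Ccl3 (1.36, 0.56 to 2.24). Il1a (1.96), Purb (1.87), Cd44 (1.64), the neutrophil-attracting chemokine Cxcl1 (1.55, 1.03 to 2.11), Pde4b (1.30) and the NF-kB inhibitor Nfkbia (0.77) were picked by size on the higher side. Relch (-1.42), Pebp1 (-1.41), the B cell-attracting chemokine Cxcl13 (-1.30), Jun (-1.15), Btg2 (-1.07) and Fos (-1.01) were picked on the lower side. Hormone RNA of islet cells differed in these cells as well, with Gcg at 1.65 (1.37 to 1.95), Sst at -0.77 and Ppy at -4.76 from 43 and 2 UMIs. The homeostatic list had -0.16 (percentile 8.83), with 6 of 7 lower. Of 1322 genes 21 were at least 2-fold higher and 25 lower in 281 HAMS against 387 HAMSAB cells, against 5.95 from counting error alone.

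In cDC-like cells, held by clusters 1 and 8, cell cycle genes had a median of 0.68 (percentile 99.9; 7 measured), with Pcna at 2.14 from 6 and 45 UMIs and Top2a at 1.25. Cluster 1 held the most of these cells in HAMS (57.7%) and cluster 8 in HAMSAB (52.1%). Cluster 8 was led by Ptgs2, Nlrp3 and Nrp2, which were not compared. Immediate early genes had 0.41 (percentile 99.9), with Ier2 at 1.64, but between 0.04 and 0.15 under 7 other ways of filtering, clustering or classing the cells, where 38.9% to 76.5% of the cDC-like cells came from cluster 6. The inflammatory list had -0.12. Nono (1.93), Cxcl2 (1.13) and Rasgef1b (1.06) were higher, and Rnf121 (-1.82), Zscan26 (-1.52), Usp9x (-1.18), Tet2 (-1.09) and the interleukin 1 receptor antagonist gene Il1rn (-1.01) lower. Zfp36l2 had 2.04 on 7 and 49 UMIs, and was below 0 under the same 7 alternatives. Of 1392 genes 46 were at least 2-fold higher and 21 lower, against 7.85 from counting error alone. In the 33 and 67 pDC-like cells the list of pDC function genes had a median of 0.60 (percentile 98.8) over 6 members, all higher, with Siglech at 0.34 (-0.18 to 0.89). Of the list's members, measured or not, Siglech, Bst2 (from 3 and 23 UMIs), Ccr9 (0.72), Tcf4, Cox6a2 and Spib are also pDC markers used to name clusters. Klk1, another of these markers, was at -0.83 (-1.98 to 0.33) from 14 and 15 UMIs. Outside the list Cybb (1.04) and Wnk1 (1.36) were higher and Cd74 lower (-0.70). Islet hormone RNA differed strongly in these few cells, with Ins2 at -3.40 from 61 and 11 UMIs and Gcg at 3.71 from 2 and 50 UMIs, while in cDC-like cells Ins2 was at -1.13 and Gcg at -0.71.

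**Figure D3:**
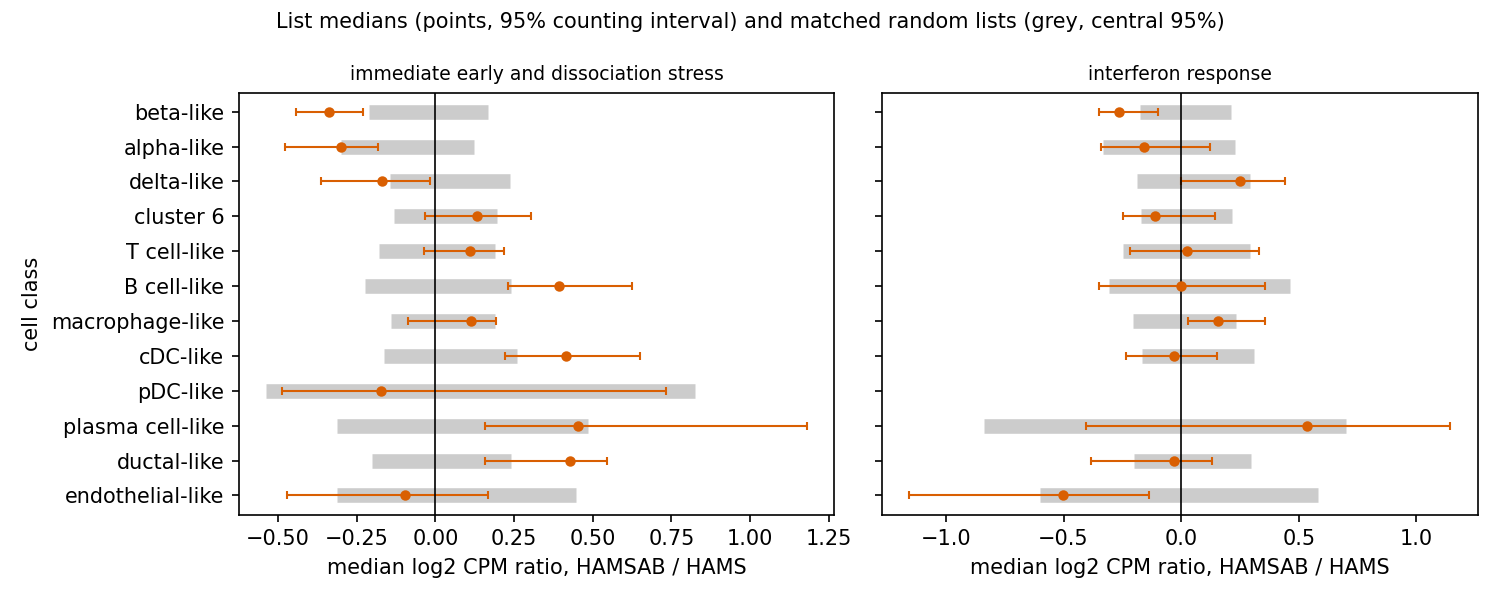
Median log2 CPM ratio of HAMSAB over HAMS (horizontal axis) of the immediate early list and the interferon list in each class (vertical axis), as points with 95% counting intervals, over grey bars that span the central 95% of matched random lists. The immediate early median was below its bar in beta-like (-0.34), alpha-like and delta-like cells and above it in B-like (0.39), cDC-like and ductal-like cells.

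The authors' deposited tables give their own comparison of the diets for 8 cell types, with p-values made over cells. For beta cells the authors' deposited table lists 115 genes, 54 higher and 61 lower on HAMSAB, with a log2 fold change of 0.66 for Iapp and 0.66 for Dnajb9. The sign of the summed CPM ratio was the same for 115 of these 115 genes of the authors' deposited table (100%), where Dnajb9 had a summed ratio of 0.72. For alpha cells the authors' deposited table has 56 genes, with -2.42 for Fos and 1.30 for Gpx3, and 55 had the same sign. For delta cells all 41 genes of the authors' deposited table had the same sign, among them Cd74 (0.47 here) and Insm1 (0.86 here). The same held for all 34 genes of the authors' deposited table of T cells, where Malat1 was at 0.74 and Rel at 1.05 here, all 27 of B cells (H3f3b 0.74, Slc38a1 0.72 and Lbr -0.54), all 37 of macrophages (Pim1 0.53 and Sat1 -0.98) and all 7 of pDCs, each lower on HAMSAB (Rps10 -2.25). For cDCs 57 of 58 genes of the authors' deposited table had the same sign in cDC-like cells and 58 of 58 in cluster 6, with Egr3 at 0.72 and Nfkbia at 0.63 in cDC-like cells. The authors' deposited tables come from the same 2 libraries and are no independent measurement. Equal signs were therefore likely in advance and are no support for the differences.

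The main genes map as follows in GENCODE M21 on GRCm38, each as a protein-coding gene. Iapp (ENSMUSG00000041681) lies on chromosome 6 from 142298423 to 142303961 and Dapl1 (ENSMUSG00000026989) on chromosome 2 from 59484653 to 59505020. Gcg (ENSMUSG00000000394) lies on chromosome 2 from 62474530 to 62483650 and Fos (ENSMUSG00000021250) on chromosome 12 from 85473890 to 85477273. Zfp36l1 (ENSMUSG00000021127) lies on chromosome 12 from 80107754 to 80113013 and Cxcl1 (ENSMUSG00000029380) on chromosome 5 from 90891241 to 90893115.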

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

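The tests on how few cells hold the Sst UMIs of beta-like cells and on the deeper alpha-like cells were written before their values were seen, the latter after the thinned alpha median was known; all other tests here were chosen after the result was seen.

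Immediate early genes stood on opposite sides of 0 by class, with a median log2 ratio of -0.34 in beta-like (-0.14, -0.41 and -0.06 within their clusters 3, 4 and 5), -0.30 in alpha-like and -0.17 in delta-like cells, and 0.43 in ductal-like and 0.39 in B-like cells of the same libraries, a difference that was not tested. The B-like median of 0.39 (0.23 to 0.62) argues against a single difference in handling or dissociation that moved every class alike. In beta-like cells with at least 1000 UMIs (324 HAMS and 283 HAMSAB cells) the median was -0.25 before and -0.39 after thinning. The lower median was thus present in these deeper cells, but 1041 HAMS and 454 HAMSAB cells were left out. Random thinning does not shift the expected ratio of summed UMIs, so it cannot decide on depth (median 673 UMIs in HAMS and 803 in HAMSAB). Depth stays open in alpha-like cells too. There the 111 HAMS and 52 HAMSAB cells with at least 1000 UMIs had a median of -0.000829 even before thinning. With no difference in them, thinning could show nothing, so the bound set beforehand for that test was wrong. The values nearer 0 within clusters 3 and 5 leave room for a different mix of beta clusters as part of the beta difference, and handling that struck endocrine cells alone, or the diet itself, may account for the rest, which was not tested.

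Sst, the hormone gene of delta cells, was lower in HAMSAB beta-like cells (log2 ratio -1.92), and Gcg and Ppy were lower too, although Sst was at 4.36 in beta cluster 5 alone and Gcg at 0.02 in cluster 4 alone. In the HAMS library 96.6% of the Sst UMIs of beta-like cells lay in the 5% of cells with the most, where free RNA spread by depth alone would put at most 19.3% in them, which argues against free RNA. The lower value in T-like cells (-1.87) shows that Sst RNA differed outside beta-like cells as well. It cannot decide on a loss of beta cell identity on HAMS, since both can hold at once, and that explanation stays open. The same 96.6% is what delta cells caught in a droplet with beta cells would give, so such doublets are a candidate explanation, although delta cells placed in a beta cluster would give it as well. Sst stayed at -2.49 without the 5% of cells with the highest Scrublet scores. Since Scrublet was taken not to have worked here, that value cannot decide on doublets. The delta share was lower by a smaller factor (0.671 of the HAMS share), so the size of the Sst difference and any part of the diet in it remain open.

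The endocrine share was 56.3% in HAMS and 29.8% in HAMSAB. If endocrine cells alone had been lost, every other class would gain by 1 factor, but the B-like share was 3.04-fold (2.60 to 3.55), the macrophage share 1.25-fold (1.07 to 1.44) and the endothelial share 0.437-fold that of HAMS. Counting every barcode removed for too few genes as endocrine would bring the HAMSAB share to 35.2%, still below the 52.7% that bounds the HAMS share from below with its own such barcodes counted as other cells. More tissue from outside the islets stays open: among cells that are not endocrine the ductal share was 1.39-fold (1.07 to 1.81) that of HAMS but the endothelial share was lower (0.272-fold), and the ductal difference shrank from 2.21 to 0.575 percentage points, and the endothelial one turned to 0.943, when each cell was classed by its own markers. Per 100 endocrine cells there were 3.18 ductal-like cells in HAMS and 13.4 in HAMSAB, a ratio that a loss of endocrine cells would raise as well. A heavier lymphocyte infiltration on HAMSAB and islets sampled at different stages of disease remain open and were not tested.

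Barcodes with too few genes, left out of every comparison, were 7.75% of the HAMSAB and 3.70% of the HAMS barcodes, and held 2.14% against 7.73% insulin UMIs and 35.9% against 28.1% Actb UMIs.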

How the results depend on the processing

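Removing cells by Scrublet, leaving Actb out of the totals and taking each beta cluster alone were tests chosen after the results were seen; the other alternatives were planned. No paired analysis was possible because the diets share replicate number 1 only, with 1 library each and no test. Over all results and alternatives, 71 shares of cells stayed within their counting intervals, 22 moved beyond them and 3 changed sign. Of the list medians 442 stayed, 43 moved and 4 changed sign, and of the single genes 1906 stayed, 277 moved and 28 changed sign. Counts of genes at least 2-fold apart stayed within 1.5 times in 114 cases and did not in 45, and the 16 values set against the authors' deposited tables all stayed. Leaving hormone genes or Actb out of the totals and centring on the median gene changed none of the medians and counts beyond these limits. Fresh clusterings and classing by single cells put 65.7% to 82.6% of cells in the same class as before. In these alternatives 38.9% to 76.5% of the cDC cells came from cluster 6, so their cDC values describe a wider class than the cDC-like cells. At resolution 0.5 all 1446 cells of cluster 6 were classed as cDC. Cells left unnamed with at least 500 genes per cell (185, of them 2 from cluster 6) and at resolution 2 (459, of them 4 from cluster 6) are not cluster 6. Their values set other cells against cluster 6, although the totals above count them among the moved and the changed signs. Shares and counts for endothelial, plasma and pDC cells have no value with at least 500 genes per cell, and thinning left too few of these cells for counts; endothelial cells also lack them at resolution 0.5. With a median near 705 UMIs per cell, low counts limit the precision of single genes, and the variation between mice was not measured. Where no cause is given below, the cause was not tested.

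With at least 500 genes per cell, which kept 1212 HAMS and 1373 HAMSAB cells, share differences in percentage points were -17.1 for endocrine, -7.07 for beta, -4.80 for alpha and -5.25 for delta cells. They were 14.6 for immune or unnamed cells, 5.66 for T cells, 12.9 for B cells, -0.0957 for macrophages and -7.50 for the cells left unnamed there. List medians in beta cells were -0.018 for granule genes, -1.96 for disallowed genes, 0.049 for the unfolded protein response and 0.34 for oxidative phosphorylation. Elsewhere they were -0.11 for delta identity, 0.42 for MHC class II and 0.71 for immediate early genes in B cells, 0.12 for immediate early genes in cDCs, 0.20 for ribosomal proteins in T cells and 0.92 for macrophage inflammatory genes. Genes at least 2-fold apart numbered 25 in ductal cells, 24 in macrophages and 140 in the unnamed cells. Single genes of changed sign were Sst in alpha cells (0.12), Ins1 (0.020), Ins2 (0.43) and Ppy (-0.36) in delta cells, Zfp36l2 in cDCs (-0.17) and Jun in the unnamed cells (0.21).

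At most 10% mitochondrial UMIs gave 4.61 points for the cDC share, 0.041 for the immediate early list in cDCs and -0.16 for Zfp36l2. Leiden resolution 0.5 gave 5.01, 0.084 and -0.071 for the same 3 results. Resolution 2 gave 4.73 points for cDCs and 5.98 for T cells, and medians of -1.42 for disallowed genes in beta cells, 0.024 for alpha identity, 0.067 for immediate early genes in cDCs and 0.49 for T cell effector genes. It left 27 genes at least 2-fold apart in its unnamed cells. Values of changed sign there were Ins1 (0.068), Ins2 (0.14) and Iapp (0.27) in alpha cells, Zfp36l2 in cDCs (-0.085), Flii (0.31) and Kcnq1ot1 (-0.29) in the unnamed cells, and Nkg7 (1.03) and Ccl5 (0.75) in T cells.

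Classing each cell by its own markers gave share differences of 19.2 points for immune cells, the same for immune or unnamed cells, -4.76 for alpha, 0.575 for ductal, 0.943 for endothelial, 5.74 for T, 7.72 for B, 1.32 for plasma cells and 1.60 for cDCs. The immediate early median was 0.18 in B cells and 0.15 in cDCs. Genes at least 2-fold apart numbered 123 in ductal, 72 in endothelial and 60 in plasma cells, 41 in cDCs and 68 in pDCs. Ins1 (0.44), Ins2 (0.49) and Iapp (0.28) in alpha cells, Ppy in delta cells (-2.08) and Zfp36l2 in cDCs (-0.082) changed sign.

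Without the cells Scrublet marked, the share difference was -4.48 points for alpha cells and 4.12 for cDCs, the immediate early median in cDCs 0.086 and Zfp36l2 -0.21. Without the 5% of cells with the highest scores, the alpha difference was -4.15 points, the cDC median 0.038, Iapp in alpha cells 0.16 and Zfp36l2 -0.25, with 3 genes at least 2-fold apart in pDCs. Equal weight per cell gave beta medians of -0.47 for disallowed and -0.33 for MHC class I genes, 0.20 for macrophage inflammatory genes, and 162 genes at least 2-fold apart in T and 164 in B cells.

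In cells thinned to 1000 UMIs the medians were -0.16 for delta identity, 0.28 for oxidative phosphorylation in beta cells, 0.0092 and -0.36 for immediate early genes in alpha and delta cells, -0.36 for T cell effector genes, and 0.88 and -0.43 for macrophage inflammatory and homeostatic genes. Fewer UMIs and cells left fewer genes to count, with 79 at least 2-fold apart in beta, 36 in alpha, 25 in ductal, 43 in T and 38 in B cells, 19 in macrophages, 27 in cDCs and 16 in cluster 6. Taking genes from 20 UMIs on added genes with wide counting error and gave 640 in beta, 391 in alpha, 377 in delta, 283 in ductal, 107 in endothelial, 487 in T, 524 in B and 131 in plasma cells, 284 in macrophages, 318 in cDCs, 61 in pDCs and 326 in cluster 6. From 200 UMIs on fewer genes were left, and the counts were 24 in beta, 12 in alpha, 7 in delta, 3 in ductal, 5 in endothelial, 9 in T, 5 in B and 5 in plasma cells, 4 in macrophages, 4 in cDCs, 0 in pDCs and 5 in cluster 6.

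In beta cluster 3 alone the medians were -0.43 for disallowed, -0.41 for interferon, -0.077 for oxidative phosphorylation, -0.14 for immediate early and -0.44 for apoptosis genes, with Ins1 at -0.45 and Ins2 at -0.52. In cluster 4 they were -0.061 for beta identity, -0.027 for granule, -0.28 for disallowed, -0.79 for interferon and -0.36 for MHC class I genes, with Gcg at 0.022. In cluster 5 they were -0.54 for interferon, 0.29 for oxidative phosphorylation, -0.089 for glycolysis, 0.32 for antioxidant, -0.060 for immediate early, 0.20 for ribosomal protein and -0.49 for apoptosis genes, with Sst at 4.36 and 58 genes at least 2-fold apart.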

Other observations

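The tests in this part were not planned, except that the gene lists and the rule that picks genes by size were fixed beforehand; ductal-like, plasma-like and cluster 6 cells were singled out after their values were seen. In ductal-like cells of the HAMSAB library, genes picked by size on the higher side included chemokine genes and Tnf, and no fixed list of such genes was read in this class. Of these genes Cxcl1 had a log2 ratio of 1.89 (1.44 to 2.37) from 45 and 383 UMIs, Cxcl2 had 1.57 (1.12 to 2.06), the monocyte-attracting chemokine Ccl2 had 1.89 from 10 and 85 UMIs, Tnf had 1.92 and Atp13a3 had 2.02. Of the 23 measured immediate early genes 19 were higher, with a median of 0.43 (percentile 99.9), while Fos was at -0.38. Lower were Ogdhl (-2.20), the apolipoprotein gene Apoa4 (-1.87), Reg1 (-1.81), Cavin1 (-1.36), the peptide-amidating enzyme gene Pam (-0.97) and Kdelr2 (-0.93), and a single cell held 33.3% of the Ogdhl, 38.6% of the Apoa4 and 37.6% of the Reg1 UMIs. Gip, the gene of an incretin hormone, had 0 UMIs in HAMS and 111 in HAMSAB, at least 16.1-fold more by a floor of 3 UMIs over the class, and all 111 came from 1 cell. Islet hormone RNA also differed in ductal-like cells, with Sst at -2.69 and Gcg at 0.82. Of 768 genes 38 were at least 2-fold higher and 13 lower, against 6.10 from counting error alone.

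Cluster 6 carried MHC class II RNA at the level of cDC-like cells, with H2-Ab1 at 3833 CPM in HAMS and 4061 in HAMSAB against 3804 and 4184 in cDC-like cells, and Cpa3, a mast cell protease gene, had no UMI in either. Of the cDC markers, Flt3 was at 105 and 138 CPM against 72.2 and 90.3 in cDC-like cells. Zbtb46 was at 135 and 71.7 against 125 and 64.9, and Itgax at 146 and 129 against 91.5 and 155. In the HAMSAB library its cells held more RNA of Gpr3 (2.01, 1.13 to 2.99), St8sia1 (19 and 64 UMIs), the heat shock gene Hsph1 (1.47), Kcnq1ot1 (1.28), the prostaglandin synthase gene Ptgs2 (1.16, 0.85 to 1.47) and Egr3 (0.79). Flii (-2.28), Sept10 (-1.90), Atxn10 (-1.50), Lrrk2 (-1.33), Lzts1 (-1.10) and Jun (-1.05) were lower. The other clusterings left no cluster that matches this one unnamed, so these values have no counterpart there. Ins2 was at -1.23 and Sst at -1.71 in cluster 6. Of 2328 genes 23 were at least 2-fold higher and 20 lower, against 8.20 from counting error alone. In the 21 HAMS and 61 HAMSAB plasma-like cells all 6 measured cell cycle genes were higher, with a median of 0.69 (percentile 97.7) and Mki67 at 2.66 (0.72 to 5.74) from 2 and 45 UMIs. Hspa8 was at 4.12 (1.59 to 9.44) from 1 and 62 UMIs and Slpi at 1.27, while the chaperone gene Hspa5 was at -0.52. In the same cells Gcg was at 3.93 from 10 and 543 UMIs and Sst at -5.48 from 288 and 23 UMIs, so RNA of islet cells differed between the libraries there. Of 220 genes 17 were at least 2-fold higher and 5 lower, against 5.60 from counting error alone.

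A gamma-like cluster, picked by its Ppy and Pyy RNA, stood apart once the 4 cells that Scrublet marked were removed, and held 112 HAMS and 56 HAMSAB cells, with Fos at -2.08. Hormones of other islet cells were lower in the same cells, with Sst at -2.81, Ins2 at -2.65, Ins1 at -2.27, Iapp at -1.36 and Gcg at -0.62. In the mixed endothelial-like cluster Ins2 was at -4.11 and Col1a1 at 4.60, with 48.4% of the Col1a1 UMIs in a single cell; 5 of its 134 genes were at least 2-fold higher and 17 lower, against 0.95 from counting error alone. In pDC-like cells 4 of 97 genes were at least 2-fold higher and 1 lower, against 0.80.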
